A study of Mus musculus with 105 samples.

How the data were processed

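Stranded total RNA sequencing of sorted mouse regulatory T cells was read from 2 tables that hold the same 105 libraries, 12 of expanded cultures, 71 of cells re-isolated from 24 recipients and 22 of resident cells. The first table holds raw read counts per Ensembl gene, as deposited, with 53465 genes. Per the submitters' processing notes the reads were processed with bcl2fastq, STAR 2.5.3a, edgeR 3.34.0 and R 4.1.0 on genome build GRCm38.p5. The gene annotation, the counting tool and the strand setting are not given in the sources used here, so overlapping genes on opposite strands and close paralogs are uncertain. The second table holds 16378 genes that the authors normalized, as log2 of reads per kilobase, scaled by library size (RPKM). Set against the counts, its values carry a further shift per gene that libraries with the same number of second PCR cycles share. Over 3023 genes with at least 300.0 counts the lowest correlation of these shifts within a cycle number was 0.99991, and the highest between cycle numbers 0.641. The normalized table served only as an alternative.

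Groups follow the labels: culture type and pool for expanded cells, model, tissue, culture type and recipient for re-isolated cells, and tissue, CD62L gate and mouse for resident cells. For 1 GvHD liver library the title and the recipient field give different recipients, and the recipient field was followed. Total counts per library had a median of 14156200, and ribosomal and similar small RNA genes took 9.41 to 29.2 % of them (median 17.2 %). Where a group holds 4 to 6 libraries, 2-fold changes were found less reliably than 4-fold ones in tests on simulated data, as given beside the comparisons that called few genes. The simulated changes lay in 200 genes well above the count filter, with no structure by pair or experiment. Recovery in the real data may be lower.

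Each comparison was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the libraries compared, with TMM factors and genes kept by filterByExpr at a minimum count of 10. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Tissue and model comparisons held the culture type as a further term. Poly and allo cells after transfer were tested on counts summed per donor culture, since the stimulus was applied to a culture, with the model as a term. Differences of the tissue change between the models were tested as an interaction. Standard errors are the log2 fold change divided by the root of F. CPM values use TMM factors over all libraries, and principal components used log2 CPM of genes with a mean of at least 5 CPM. Gene positions are those of GENCODE vM21 on GRCm38.

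Before the data were examined, 25 gene lists with 374 genes were written down, of which 2 had no entry in the counts. They cover Treg identity, effector and tissue Treg, lymphoid and naive T cell, gut homing and colonic Treg, liver homing, interferon response, cell cycle, cytotoxic and effector molecules, Th1, Th2, Th17, inhibitory receptors, glycolysis, cholesterol synthesis, oxidative phosphorylation, early response and dissociation, AP-1 and NF-kB activation, and markers of hepatocytes, colon epithelium, B and plasma cells, myeloid, dendritic, erythroid, CD8 T and NK cells, and endothelium and stroma. Members called are counted over all genes and with p adjusted over the list alone. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, adjusted over the lists.

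The genes named were chosen by a rule set at the same time. For each comparison they come from the 4 largest rises and the 4 largest falls among called genes with at least 20 mean CPM in the higher group, those without overlap first. Further sources are the 2 called members of each list with the smallest p (or the 1 with the smallest p where none is called), and Foxp3, Il2ra, Ikzf2, Ctla4 and Mki67. Some genes that the rule picks, and results that rest on them, are not reported here. Predicted genes, receptor and immunoglobulin segments, histone, ribosomal and mitochondrial genes were left out of the first part.

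Libraries are paired by pool, experiment, recipient or mouse. Whether they share more than chance was checked by correlating centred log2 CPM within pairs. Over 6 pools of expanded cultures the median r was 0.352, over 4 mice of the liver gates 0.363, over 12 recipients of BMT colon and spleen -0.0551. It was 0.483 over 4 mice of the spleen gates. For poly against allo cells after transfer, with 4 pairs by experiment, it was higher, at 0.618 in spleen, 0.418 in liver and 0.604 in colon. The main fits leave these pairs aside. Fits with the pair as a block served as alternatives. Further alternatives were RLE size factors, the Wald test of DESeq2 1.42.0, limma on the normalized table, no filter on low counts, the number of second PCR cycles as a term, counts summed per culture, each model alone, and leaving out each experiment or replicate in turn. The data cannot part model from experiment, as the recipients of each model come from their own experiments. Reads, single cells and other kinds of data were not used here.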

Results

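Regulatory T cells, the CD4 T cells that carry the transcription factor Foxp3 and restrain other T cells, were profiled by stranded total RNA sequencing in 105 mouse libraries, with reads counted per gene. The study asks how transferred donor cells adapt to the tissues of the recipient, and its libraries are of 3 kinds. Expanded cells are 6 allo cultures, grown with irradiated CD11c-positive dendritic cells of BALB/c mice, and 6 poly cultures, grown with CD3/CD28 beads. Re-isolated cells were recovered 7 days after transfer into BALB/c recipients, which were bone marrow transplant controls (BMT) or had acute graft-versus-host disease (GvHD), in which donor T cells attack the host. From spleen, liver and colon of each model there are 6 libraries of allo and 6 of poly cells, with 5 for poly cells of GvHD liver. Resident cells come from C57BL/6 mice in the homeostatic state. They are 5 colon libraries without CD62L (the surface protein used to gate them), 5 liver libraries with and 4 without it, and 4 spleen libraries of each gate. Total counts per library ran from 7792440 to 43519000, with a median of 14156200.

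Foxp3 (ENSMUSG00000039521.12; GRCm38 chromosome X, 7573644 to 7595245, protein-coding) was present in all 105 libraries, at 272 to 716 CPM (counts scaled by library size). Group means of Foxp3 ran from 347 ± 46.7 CPM (SD, n = 6) in allo cells of GvHD liver to 633 ± 69.7 (SD, n = 5) in resident colon. The first principal component held 33.5 % of the variance of 9767 genes and the second 20.2 %. Values are given as mean CPM ± SD over libraries and as log2 fold changes ± standard error, with p adjusted over all genes of a comparison. A gene rose or fell where its adjusted p was under 0.05, and the amounts after these words are log2 fold changes.

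**Figure D1:**
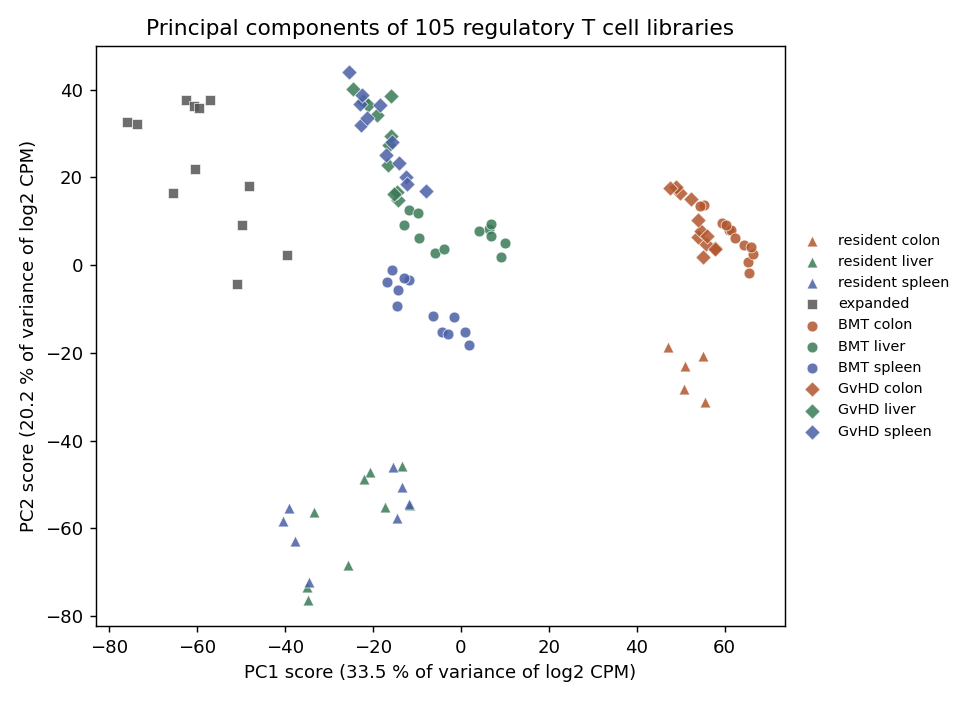
Principal components 1 (33.5 % of variance) and 2 (20.2 %) of log2 CPM, 1 point per library, with colour for tissue and marker for resident, expanded, BMT and GvHD cells. Each of the 105 libraries is drawn.

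Expanded cells were compared to ask how the stimulus shapes the product before transfer. Allo cultures held more of several effector genes. Penk (ENSMUSG00000045573.9; chromosome 4, 4133531 to 4138819), which encodes the opioid precursor proenkephalin, averaged 18.1 ± 8.08 CPM in 6 allo and 0.722 ± 0.522 in 6 poly cultures (log2 fold change of poly over allo -4.76 ± 0.49, adjusted p = 0.000200). The chemokine gene Ccl22 was at 24.1 ± 15.3 CPM in allo and 0.0173 ± 0.0423 in poly cultures. Nfil3, a transcription factor of activated T cells, fell by 1.82 ± 0.26 in poly cultures (adjusted p = 0.00195), and the inhibitory receptor gene Lag3 fell by 2.74 ± 0.36 (adjusted p = 0.00110). The chemokine gene Ccl5 and Ccr4, which encodes the receptor for Ccl22, were lower in poly cultures, with log2 fold changes of -3.75 ± 0.44 and -1.14 ± 0.17. Poly cultures held more Il6ra, the interleukin 6 receptor gene (log2 fold change 1.40 ± 0.15, adjusted p = 0.000307) and more of the RNA-binding gene Igf2bp2 (1.23 ± 0.14, adjusted p = 0.000307). Neither gene overlapped between the cultures, which 1 gene in 462 shows by chance with the pools left aside. The naming rule favours such genes, so this is no test of them. The lymph node receptor gene Ccr7 rose by 0.86 ± 0.19 (adjusted p = 0.0253). Of genes of effector and tissue regulatory T cells, 7 of 17 fell and 0 rose (11 adjusted over the list alone; median -0.57, camera adjusted p = 1.88e-15, adjusted p = 0.0182 with an estimated correlation and 0.0731 with it when paired). Of genes of lymphoid and naive T cells, 2 of 15 rose (4 adjusted over the list alone; median 0.70, camera adjusted p = 2.40e-06, adjusted p = 0.128 with an estimated correlation). No member of the glycolysis list passed the test (0 of 17, 8 fell adjusted over the list alone), while the paired fit called 13 lower in poly cultures (median -0.80, camera adjusted p = 2.98e-09, adjusted p = 0.212 with an estimated correlation). The nuclear receptor Nr4a3 and the zinc finger factor Egr3, both induced by the T cell receptor, gave -1.54 ± 0.25 and -1.74 ± 0.27. The class II chaperone Cd74, abundant in dendritic cells, was at 9.34 ± 3.69 CPM in allo and 1.95 ± 0.720 in poly cultures. The haemoglobin gene Hbb-bt was at 20.6 ± 9.55 against 3.83 ± 2.56, and the B cell gene Ebf1 at 2.18 ± 1.17 against 0.305 ± 0.201. The endothelial gene Pecam1 was not called (0.37 ± 0.17, adjusted p = 0.354). Only allo cultures were grown with dendritic cells, so in genes higher there, such as Ccl22, RNA of other cells cannot be told apart from that of the T cells. Foxp3 missed the threshold (log2 fold change 0.40 ± 0.12, adjusted p = 0.118), but passed it paired by pool (0.40 ± 0.09, adjusted p = 0.0388). In all, 318 of 12698 genes differed, 66 higher and 252 lower in poly cultures. The paired fit called 596 and DESeq2 657, and leaving out experiment 4, 5, 6 or 7 gave 132, 157, 133 or 175.

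Resident spleen cells without CD62L were set against those with it to describe the effector state that mice hold without transplant. CD62L-negative cells held far more Penk (log2 fold change 4.02 ± 0.11, adjusted p = 3.79e-10), more Tigit, an inhibitory receptor gene (5.62 ± 0.16, adjusted p = 4.26e-10), and more of the interleukin 18 receptor gene Il18rap (3.85 ± 0.14, adjusted p = 1.78e-09). The lectin-like receptor Klrg1 was at 31.1 ± 5.55 CPM against 0.290 ± 0.187. S1pr1, the receptor for exit from lymphoid tissue, fell by 3.08 ± 0.11 (adjusted p = 1.72e-09), and the chromatin organiser Satb1 fell by 2.97 ± 0.10 (adjusted p = 1.72e-09). Each of these genes parted the 4 libraries of one gate from the 4 of the other. By chance 1 gene in 35 does so with the mice left aside, but the naming rule favours such genes, so this is no test. All 19 measured effector and tissue genes rose (19 adjusted over the list alone; median 2.28, camera adjusted p = 5.98e-59), and 15 of 16 lymphoid and naive genes fell with 1 higher (1 and 15 adjusted over the list alone). Cholesterol synthesis fell in 16 of 18 genes (17 adjusted over the list alone; median -0.86, camera adjusted p = 8.25e-11), among them Hmgcs1 (-1.49 ± 0.08, adjusted p = 2.64e-08). Inhibitory receptors rose in 9 of 10, and the Th1 list in 8 of 9 with the same counts adjusted over the list alone. The interferon response list had 14 of 28 members lower and 2 higher (both counts the same adjusted over the list alone; camera adjusted p = 0.000319, adjusted p = 0.282 with an estimated correlation). Ikzf2, encoding the factor Helios, rose by 0.94 ± 0.10 and Il2ra, the CD25 gene, fell by 0.47 ± 0.08. Foxp3 did not pass (-0.12 ± 0.08, adjusted p = 0.304). The test called 4262 of 13582 genes, 2313 of them higher without CD62L.

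The same gates in resident liver asked whether the liver holds the 2 states as well. There edgeR called 0 of 14275 genes, 939 had an unadjusted p under 0.05, and DESeq2 and limma called 0 and 0. Paired by mouse, 531 genes were called, but the block also takes CD62L-positive replicate 3, whose mouse has no CD62L-negative library, out of the contrast between the gates. Itgae, the CD103 integrin gene, was at 119.6 ± 17.0 CPM in 4 CD62L-negative and 51.6 ± 28.0 in 5 CD62L-positive libraries without overlap (log2 fold change 1.20 ± 0.33, adjusted p = 0.728, and blocked 1.61 ± 0.24, adjusted p = 0.00149). By chance 1 gene in 63 parts these gates with the mice left aside, but Itgae was picked by its p, so this is no test of it. Ikzf2 gave 0.72 ± 0.25, adjusted p = 0.728 and 1.05 ± 0.13, adjusted p = 0.000403 with the block. The paired fit called 14 of 20 effector and tissue genes higher and 12 of 16 lymphoid and naive genes lower, against 0 of each unpaired (0 and 12 adjusted over the list alone, with 1 naive gene higher so and when paired; unpaired medians 0.58 and -0.71). By camera the adjusted p of these lists was 1.41e-10 and 1.64e-15 (adjusted p = 0.193 and 0.142 with an estimated correlation). With no filter on low counts 192 genes were called, and without CD62L-positive replicate 3 the unpaired test called 275 genes. On simulated changes of 2-fold, in genes well above the count filter, the unpaired test recovered 45 % and of 4-fold 89 %.

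What marks resident cells of the colon was read against CD62L-negative spleen cells. These colon and spleen libraries came mostly from different mice, so they were not paired and differences between mice were not removed. All resident colon and liver libraries had 14 second PCR cycles and all resident spleen libraries 12, so tissue and cycle number cannot be told apart in resident cells. Il1rl1 (ENSMUSG00000026069.15; chromosome 1, 40429570 to 40465415), the receptor gene for interleukin 33, averaged 1581 ± 220.5 CPM in 5 colon and 34.3 ± 5.36 in 4 spleen libraries (log2 fold change 5.61 ± 0.16, adjusted p = 3.93e-12). Rora (ENSMUSG00000032238.17; chromosome 9, 68653786 to 69388246), a nuclear receptor, rose to 1944 ± 80.1 from 122 ± 8.48 CPM (4.09 ± 0.09, adjusted p = 5.13e-13). The neuropeptide gene Calca, which encodes CGRP, and the receptor partner Ramp3 were at 333 ± 69.0 and 309.9 ± 79.8 CPM in colon and at 0.262 ± 0.0882 and 0.680 ± 0.560 in spleen. The cytokine gene Il5 stood at 75.4 ± 22.0 CPM against 0.0309 ± 0.0617. Receptors Ccr2 and Cxcr6, which guide cells into tissue, rose by 5.37 ± 0.23 and 4.50 ± 0.16, Havcr2 (the checkpoint TIM-3) by 5.85 ± 0.24 and Ctla4, an inhibitory receptor of regulatory T cells, by 2.44 ± 0.12. The folate receptor gene Izumo1r fell by 2.97 ± 0.11. In the effector and tissue list 19 of 20 rose and 1 fell (19 and 1 adjusted over the list alone; median 2.31, camera adjusted p = 3.36e-38). All 10 measured Th2 genes rose (10 adjusted over the list alone; median 2.84, camera adjusted p = 4.24e-22), with 8 of 9 Th17 genes and 13 of 16 gut homing genes, the last with 1 lower (list-alone counts equal). Early response genes, which dissociation of tissue can also induce, rose in 17 of 20 with 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 3.09e-09). Transcripts of other cells moved with the colon: the light chain gene Igkc was at 608 ± 435 CPM against 3.46 ± 1.10, macrophage lysozyme Lyz2 at 25.1 ± 14.5 against 0.760 ± 0.143, and 10 of 10 endothelium and stroma genes rose (10 adjusted over the list alone; camera adjusted p = 0.0149, adjusted p = 0.547 with an estimated correlation). The test called 6624 of 14324 genes, 3576 higher in colon.

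Resident liver cells, compared with the same spleen libraries, held more of the genes of recirculating cells. S1pr1 averaged 407 ± 76.9 CPM in 4 liver and 56.6 ± 6.89 in 4 spleen libraries (log2 fold change 2.93 ± 0.13, adjusted p = 1.12e-08). Its regulator Klf2 rose by 3.30 ± 0.20 (adjusted p = 6.22e-08). Ccr2 rose by 3.75 ± 0.19 and Il1rl1 by 2.54 ± 0.13, to 187 ± 21.1 CPM. The protease gene Gzmb, encoding granzyme B, was at 14.0 ± 5.44 against 1.29 ± 0.256 CPM. Penk fell by 4.21 ± 0.20 (adjusted p = 1.32e-08), the costimulatory receptor gene Tnfrsf9 fell by 3.14 ± 0.17 (adjusted p = 3.40e-08), and the activation gene Cd83 fell by 3.06 ± 0.17 (adjusted p = 3.40e-08). CD62L-positive cells in the CD62L-negative liver libraries could give such changes too, and were not told apart from a state of liver cells. In CD62L-positive spleen cells S1pr1 was at 480 ± 40.2 CPM, Penk at 10.6 ± 1.46, Tnfrsf9 at 54.3 ± 7.95 and Cd83 at 34.3 ± 5.19. Each lay on the liver side of CD62L-negative spleen cells. Rora, the interleukin 18 receptor gene Il18r1 and Ccl5 went the other way. They were at 257 ± 39.3, 279 ± 41.2 and 50.7 ± 11.0 CPM in liver. CD62L-negative spleen cells held 122 ± 8.48, 129 ± 6.96 and 11.0 ± 2.63, and CD62L-positive ones 27.2 ± 1.14, 39.1 ± 0.882 and 0.980 ± 0.136. Cells like the CD62L-positive spleen cells would lower these genes, so they alone do not give these rises. Klf2, Ccr2, Il1rl1 and Gzmb were not read in CD62L-positive spleen cells. Lymphoid and naive genes rose in 14 of 16 and fell in 1, or 0 when paired (15 and 1 adjusted over the list alone; median 1.53, camera adjusted p = 8.64e-22, adjusted p = 0.0567 with an estimated correlation). Liver homing genes rose in 8 of 10 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 2.14e-09, adjusted p = 0.0567 with an estimated correlation), while AP-1 and NF-kB genes of T cell activation fell in 13 of 17 (14 adjusted over the list alone; median -0.74, camera adjusted p = 1.07e-10, adjusted p = 0.0794 with an estimated correlation). The test called 3220 of 13794 genes, 1663 higher in liver, and 2079 when paired by mouse.

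Re-isolated spleen cells were compared with the expanded product to see what 7 days in a recipient change. The 24 spleen libraries are 12 of GvHD and 12 of BMT recipients, fitted together without a term for the model. All 28 interferon genes were higher in GvHD than in BMT spleen, so the values are means over unlike groups. Recipients of the same donor culture were counted as separate libraries. Most spleen libraries had more second PCR cycles than any expanded library, and the fit held no term for the cycle number. Its part in these changes was not tested. Some of the expanded cultures come from experiments without re-isolated cells. The transcription factor gene Maf averaged 589 ± 65.1 CPM in 24 spleen and 18.6 ± 6.96 in 12 expanded libraries (log2 fold change 5.01 ± 0.15, adjusted p = 7.19e-26). Th1 genes Cxcr3 and Tbx21, a chemokine receptor and the master factor of that lineage, rose by 5.31 ± 0.28 and 5.09 ± 0.28, and Klrg1 stood at 35.4 ± 11.7 CPM against 0.214 ± 0.381. Dtx1, a ubiquitin ligase gene of the Notch pathway, averaged 290.0 against 0.403 CPM. Cells after transfer held less Il2ra, which fell by 1.99 ± 0.11 (adjusted p = 6.77e-18), less Myc (-2.86 ± 0.13, adjusted p = 2.19e-20), and far less of the hypoxia and mitophagy gene Bnip3 (-5.65 ± 0.23, adjusted p = 1.04e-21). The desaturase gene Scd1 was at 0.466 ± 0.426 CPM against 87.6 ± 52.2. Glycolysis fell in 16 of 17 genes (16 adjusted over the list alone; mean -2.07, camera adjusted p = 1.14e-10, adjusted p = 0.161 with an estimated correlation) and cholesterol synthesis in 17 of 18 (17 adjusted over the list alone; median -1.96, camera adjusted p = 7.70e-16, adjusted p = 0.0728 with an estimated correlation). Effector and tissue genes rose in 18 of 20 (18 adjusted over the list alone; camera adjusted p = 6.75e-13), inhibitory receptors in all 10 (10 adjusted over the list alone; camera adjusted p = 6.83e-06), and interferon genes in 24 of 28 (24 adjusted over the list alone; camera adjusted p = 6.35e-09, adjusted p = 0.254 with an estimated correlation). Foxp3 did not pass (-0.11 ± 0.07, adjusted p = 0.150). Spleen libraries also carried transcripts of erythroid cells, with Hbb-bs at 145 ± 160.1 (268 ± 142 in GvHD spleen alone) against 0.00667 ± 0.0231 CPM, and 11 of 12 myeloid genes rose with 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.000383, adjusted p = 0.263 with an estimated correlation). In all 9732 of 13741 genes differed, 4876 of them higher after transfer.

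Cells from the colon of BMT recipients were set against spleen cells of the same 12 mice to describe adaptation to the gut without disease. Rora rose to 2215 ± 329 CPM in 12 colon libraries from 159.5 ± 15.3 in 12 spleen libraries (log2 fold change 3.83 ± 0.07, adjusted p = 1.52e-25). Tnfrsf9 rose by 2.63 ± 0.05 (adjusted p = 4.83e-24), Cxcr6 by 3.05 ± 0.14, the lipid receptor gene Gpr55 by 3.21 ± 0.08 and Ctla4 (ENSMUSG00000026011.13; chromosome 1, 60887000 to 60915832) by 2.19 ± 0.13, to 1465 ± 199 CPM. The checkpoint gene Pdcd1 rose by 2.28 ± 0.08, while Lag3 fell by 1.83 ± 0.08. Il6ra fell by 4.20 ± 0.16, and Nrp1, a surface marker of thymic regulatory T cells, fell by 2.49 ± 0.07. In each of these genes the 12 colon libraries lay apart from the 12 spleen libraries. Glycolysis rose in 16 of 17 genes with 1 lower (16 and 1 adjusted over the list alone; median 1.15, camera adjusted p = 2.70e-14), Aldoa by 1.55 ± 0.04. The Th1 list rose in 9 of 10 (9 and 1 adjusted over the list alone; camera adjusted p = 1.02e-08) and the effector and tissue list in 14 of 20 with 2 lower (14 and 2 adjusted over the list alone; camera adjusted p = 1.70e-10). Colon epithelial transcripts were plentiful, with the keratin gene Krt8 at 216 ± 119 CPM in colon and 0.0213 ± 0.0499 in spleen, Dmbt1 at 417 ± 272 and 0.00519 ± 0.0180, and all 14 measured epithelial genes higher (14 adjusted over the list alone; camera adjusted p = 9.16e-06, adjusted p = 0.406 with an estimated correlation and 0.0206 with it when paired). The collagen genes Col3a1 and Col1a2 of stromal cells were at 75.2 ± 79.4 and 23.6 ± 24.8 CPM in colon and 0.0213 ± 0.0316 and 0.171 ± 0.158 in spleen. The test called 10115 of 13340 genes, 4979 higher in colon. Without colon libraries above 1000 CPM of epithelial markers it called 9070.

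Liver cells of the same BMT recipients held more transcripts of dividing cells than spleen cells. Mki67 (ENSMUSG00000031004.8; chromosome 7, 135689784 to 135716361), a proliferation marker, averaged 1027 ± 338 CPM in 12 liver and 425 ± 179 in 12 spleen libraries (log2 fold change 1.30 ± 0.20, adjusted p = 7.93e-06). Pcna, a replication clamp gene, rose by 0.77 ± 0.07 without overlap, and 27 of 28 cell cycle genes rose (28 adjusted over the list alone; median 1.16, camera adjusted p = 4.73e-15, adjusted p = 0.104 with an estimated correlation and 0.0357 with it when paired). The nuclear lamina gene Lmna rose by 2.21 ± 0.23, annexin Anxa2 by 1.00 ± 0.07, Rora by 1.12 ± 0.11 and Il1rl1 by 0.95 ± 0.06. The signalling gene Tbc1d4 fell by 2.18 ± 0.10 (adjusted p = 3.32e-15), the inhibitory receptor gene Btla fell by 1.09 ± 0.08 and the naive cell factor Tcf7 fell by 0.97 ± 0.09. Liver homing genes rose in 8 of 10 with 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.000637), cytotoxic and effector molecules in 12 of 17 with 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 1.71e-08). Macrophage genes C1qc and Csf1r were at 0.0104 ± 0.0244 and 0.0420 ± 0.0489 CPM in liver and at 7.34 ± 2.49 and 6.71 ± 2.26 in spleen. The test called 5040 of 13219 genes, 2696 higher in liver. With the number of second PCR cycles as a term it called 3102, or 2705 with 1 level per number.

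In GvHD the colon cells, again read against spleen cells of the same 12 mice, held far less of the cell cycle genes. Mki67 was at 171 ± 29.5 CPM in 12 colon and 1605 ± 345 in 12 spleen libraries (log2 fold change -3.20 ± 0.11, adjusted p = 2.50e-19), the kinetochore motor gene Cenpe fell by 3.62 ± 0.14, and all 28 cell cycle genes fell (28 adjusted over the list alone; median -3.36, camera adjusted p = 4.14e-39). Ctla4 rose to 2764 ± 359 CPM (2.50 ± 0.08, adjusted p = 2.69e-20), Lrrc32, which presents TGF-beta, by 2.31 ± 0.09 (adjusted p = 4.09e-18), and the tissue repair ligand Areg by 3.76 ± 0.13 (adjusted p = 2.06e-19). Rora rose by 3.44 ± 0.12, and Calca and Ramp3 stood at 106 ± 80.8 and 149 ± 18.7 CPM against 0.707 ± 0.369 and 1.88 ± 0.729 in spleen. The death ligand gene Fasl rose by 2.49 ± 0.12. Colon and spleen libraries did not overlap for any of these genes. Foxp3 itself rose by 0.31 ± 0.07 (adjusted p = 0.000321). Interferon genes fell in 23 of 28 with 1 higher, or 0 when paired (1 and 23 adjusted over the list alone; median -0.73, camera adjusted p = 2.59e-07, adjusted p = 0.0801 with an estimated correlation and 0.00118 with it when paired), and the GTPase gene Irgm1 fell by 1.74 ± 0.10. AP-1 and NF-kB genes rose in 13 of 17 with 3 lower (13 and 3 adjusted over the list alone; camera adjusted p = 1.11e-07). Erythroid genes were spleen transcripts, with Slc4a1 at 191 ± 111 CPM there and 0.0388 ± 0.0738 in colon, and all 10 fell (10 adjusted over the list alone; camera adjusted p = 7.48e-15). The macrophage genes Csf1r and C1qc were also lower in colon, at 0.614 ± 0.597 and 0.839 ± 0.807 against 22.7 ± 11.8 and 18.1 ± 8.33 CPM. Epithelial genes were higher in 4 of 6 (4 adjusted over the list alone; camera adjusted p = 0.119), the mucin gene Muc2 at 74.8 ± 82.6 against 0.176 ± 0.431 CPM. The test called 7925 of 12576 genes, 3978 higher in colon, and 852 when 1 spleen library, the only one under 500 CPM of erythroid markers, was kept.

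GvHD liver cells held less of several activation genes than their spleen counterparts, while erythroid and myeloid transcripts fell as well. Itga1, the collagen receptor integrin of tissue lymphocytes, rose to 46.5 ± 8.73 CPM in 11 liver libraries from 12.4 ± 2.98 in 12 spleen libraries (log2 fold change 1.92 ± 0.13, adjusted p = 5.13e-12), with Fasl up by 0.93 ± 0.10 and the protease gene Ctsw by 1.15 ± 0.10. Tnfrsf9 fell by 1.13 ± 0.07 (adjusted p = 1.96e-12), Lag3 fell by 1.64 ± 0.09 (adjusted p = 2.37e-13), Ccr8, a receptor of tissue regulatory T cells, fell by 1.16 ± 0.07, and Tcf7 fell by 1.65 ± 0.10. The antiviral gene Rsad2 fell by 2.48 ± 0.21 and Ctla4 fell by 0.78 ± 0.10. Of the effector and tissue list 13 of 20 fell and 4 rose (5 and 13 adjusted over the list alone; median -0.53, camera adjusted p = 1.77e-12), and AP-1 and NF-kB genes fell in 12 of 17 with 4 higher (4 and 12 adjusted over the list alone; camera adjusted p = 2.04e-09). Mki67 did not pass (0.23 ± 0.12, adjusted p = 0.185), and of the cell cycle list 0 rose and 1 fell (0 adjusted over the list alone), or 7 and 2 when paired (median 0.12, camera adjusted p = 0.269). Macrophage gene C1qc was at 0.364 ± 0.334 CPM in liver and 18.1 ± 8.33 in spleen, and 9 of 11 myeloid genes fell (9 and 1 higher adjusted over the list alone; camera adjusted p = 2.40e-16). Erythroid transcripts were lower in liver, with Slc4a1 at 0.577 ± 0.765 against 191 ± 111 and Ermap at 0.0549 ± 0.106 against 25.3 ± 14.8 CPM, and all 10 measured fell (10 adjusted over the list alone; camera adjusted p = 4.17e-29). Calls numbered 3177 of 12889, 1559 higher in liver, 2004 without experiment 3 and 1932 with the PCR cycle number as a factor. They numbered 1877 without the 6 spleen libraries highest in erythroid markers, and 218 with the 1 spleen library under 500 CPM of them.

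Whether the changes from spleen differ between the models was tested as the change from spleen in GvHD minus that in BMT recipients. In the colon, Mki67 went to 171 ± 29.5 from 1605 ± 345 CPM in GvHD and to 278 ± 76.3 from 425 ± 179 in BMT recipients (difference -2.60 ± 0.23, adjusted p = 1.17e-12; 12 libraries per tissue and model). The topoisomerase gene Top2a gave -2.56 ± 0.21, adjusted p = 9.00e-14, and all 28 cell cycle genes were lower in GvHD by this test (28 adjusted over the list alone; median -2.58, camera adjusted p = 2.69e-30, adjusted p = 0.0349 with an estimated correlation and 0.0629 with it when paired). The glycolysis list was lower in 14 of 17 (14 adjusted over the list alone; camera adjusted p = 1.13e-09, adjusted p = 0.102 with an estimated correlation and 0.000219 with it when paired) and the interferon list in 21 of 28 (22 adjusted over the list alone; camera adjusted p = 1.52e-09, adjusted p = 0.102 with an estimated correlation). The survival gene Bcl2 moved the other way (1.78 ± 0.14, adjusted p = 1.14e-14), as did Dtx1 (2.22 ± 0.24, adjusted p = 1.53e-10). The class II chaperone Cd74 gave -1.74 ± 0.14, adjusted p = 2.44e-14, and dendritic cell genes were lower in 8 of 8 (8 adjusted over the list alone; camera adjusted p = 2.66e-06, adjusted p = 0.00807 with an estimated correlation and 0.0517 with it when paired). This test called 7029 of 14497 genes, 3168 higher in GvHD, 4068 without experiment 7, 3844 without colon libraries above 1000 CPM of epithelial markers, and 1177 with the 1 GvHD spleen library under 500 CPM of erythroid markers. In the liver the early response gene Nr4a1 went to 71.9 ± 11.1 from 124 ± 29.5 CPM in GvHD and to 422 ± 263 from 165 ± 81.9 in BMT recipients (-2.17 ± 0.37, adjusted p = 3.40e-05). The suppressive cytokine gene Il10 gave -2.16 ± 0.31, adjusted p = 1.29e-06, the stress gene Gadd45b -2.34 ± 0.31, adjusted p = 3.04e-07, and Bcl2 1.35 ± 0.16, adjusted p = 3.13e-08. Early response genes were lower in 13 of 20 with 0 higher, or 1 when paired (14 adjusted over the list alone; median -1.10, camera adjusted p = 5.90e-10, adjusted p = 0.306 with an estimated correlation and 0.00145 with it when paired) and cell cycle genes in 26 of 28 (28 adjusted over the list alone; camera adjusted p = 2.06e-19, adjusted p = 0.182 with an estimated correlation and 0.0152 with it when paired). Dissociation of tissue can also induce early response genes, and handling in different experiments cannot be told apart from the model. The liver test called 2362 of 14395 genes, 1007 higher in GvHD, and 1302, 1241 or 1491 without experiment 2, 3 or 7. It called 1113 without the 6 GvHD spleen libraries highest in erythroid markers, and 127 with the 1 such library under 500 CPM of them.

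**Figure D2:**
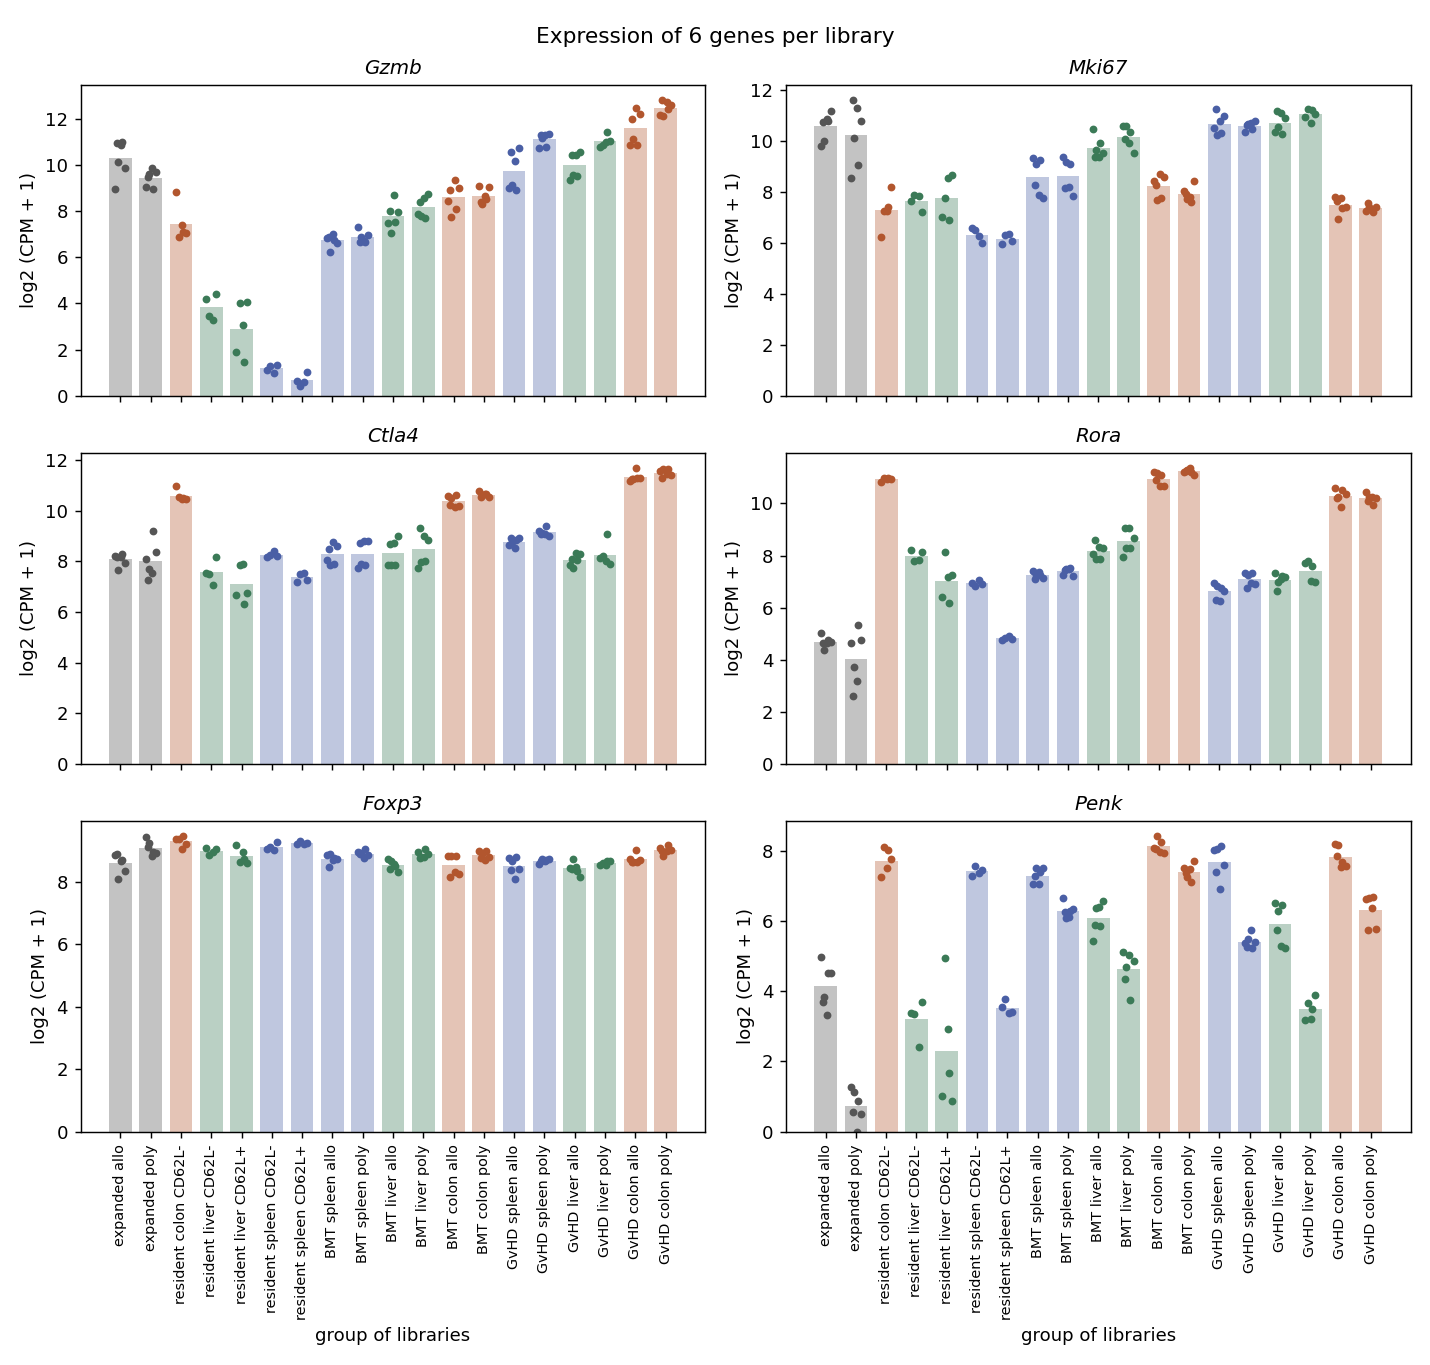
Log2 (CPM + 1) of Gzmb, Mki67, Ctla4, Rora, Foxp3 and Penk, 1 point per library, with group means as bars, in expanded, resident and re-isolated cells. Mki67 averaged 1605 ± 345 CPM in 12 libraries of GvHD spleen and 171 ± 29.5 in 12 of GvHD colon.

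Direct comparison of the models in the spleen asked what disease adds to transfer. Gzmb (ENSMUSG00000015437.5; chromosome 14, 56258838 to 56262260) averaged 1612 ± 801 CPM in 12 GvHD and 112 ± 20.8 in 12 BMT libraries (log2 fold change 3.72 ± 0.22, adjusted p = 1.76e-12). Rsad2 rose by 2.79 ± 0.20 (adjusted p = 3.49e-11), the pore gene Prf1 by 1.97 ± 0.15, Lag3 by 1.22 ± 0.06 and Mki67 by 1.91 ± 0.19. Cd83 fell by 2.07 ± 0.22 (adjusted p = 1.25e-08), Nrp1 fell by 0.96 ± 0.08 and Id3, a factor that holds cells in a resting state, fell by 1.93 ± 0.11. GvHD and BMT libraries did not overlap for these genes. All 28 interferon genes rose (28 adjusted over the list alone; median 0.82, camera adjusted p = 2.91e-23) and all 28 cell cycle genes (28 adjusted over the list alone; median 2.01, camera adjusted p = 9.02e-28, adjusted p = 0.0741 with an estimated correlation). Oxidative phosphorylation rose in 19 of 20 (19 adjusted over the list alone; camera adjusted p = 7.66e-06, adjusted p = 0.292 with an estimated correlation) and glycolysis in 15 of 17 with 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 1.87e-07, adjusted p = 0.198 with an estimated correlation). Foxp3 fell by 0.23 ± 0.05 (adjusted p = 0.000622), while Il2ra rose by 0.53 ± 0.05. Erythroid transcripts moved the same way, with Alas2 at 87.4 ± 53.5 against 5.97 ± 5.22 CPM and a sum over the list of 920.3 ± 499.8 against 73.2 ± 69.4, and all 12 myeloid genes rose (12 adjusted over the list alone; camera adjusted p = 3.38e-05). The plasma cell gene Igkc was at 88.3 ± 37.3 against 16.8 ± 8.17 CPM and H2-Ab1 of dendritic cells at 22.3 ± 5.57 against 4.89 ± 1.13. Fcer1g and Tyrobp, of NK and myeloid cells, were at 6.92 ± 3.01 and 2.37 ± 1.07 against 2.24 ± 0.842 and 1.00 ± 0.450. The test called 7977 of 13176 genes, 3860 higher in GvHD. It called 5278 without experiment 3, 5003 with counts summed per donor culture, 2905 with the erythroid sum as a term and 1394 with the 1 GvHD spleen library under 500 CPM of erythroid markers. GvHD recipients came from experiments 2 and 3 and BMT recipients from 6 and 7, so disease and experiment cannot be told apart here or in the other tissues.

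Liver cells of GvHD recipients held more transcripts of cytotoxic, interferon and cell cycle genes, and less of early response genes. Gzmb averaged 1544 ± 662 CPM in 11 GvHD and 268 ± 98.9 in 12 BMT libraries (log2 fold change 2.40 ± 0.18, adjusted p = 6.09e-11), its relative Gzma 91.5 ± 56.6 against 8.12 ± 3.92 (3.48 ± 0.23, adjusted p = 7.70e-12), and Il2ra rose by 0.80 ± 0.07 (adjusted p = 5.85e-10). Foxp3 fell by 0.25 ± 0.07 (adjusted p = 0.00639), which did not pass with the PCR cycle number as a factor (-0.16 ± 0.08, adjusted p = 0.231). Ppp1r15a, a stress phosphatase subunit gene, fell by 2.06 ± 0.15 (adjusted p = 3.63e-11), Nr4a1 fell by 2.61 ± 0.29, the NF-kB gene Rel fell by 2.10 ± 0.20 and Tcf7 fell by 1.52 ± 0.12. Cytotoxic and effector molecules rose in 10 of 17 (11 adjusted over the list alone; median 0.54, camera adjusted p = 6.24e-10). Early response genes fell in 18 of 20 (18 adjusted over the list alone; median -1.60, camera adjusted p = 4.71e-24). Dissociation of tissue can also induce them. The models come from different experiments, so handling cannot be told apart from a state of the cells. Over the 12 BMT libraries Nr4a1 ran from 96.3 to 763 CPM and Ppp1r15a from 296 to 1030. Interferon genes rose in 27 of 28 with 1 lower (27 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 4.68e-21) and cell cycle genes in 26 of 28 (27 adjusted over the list alone; median 0.98, camera adjusted p = 4.95e-25). Liver homing genes rose in 7 of 10 with 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 7.45e-06), Itga1 by 1.37 ± 0.14. Transcripts of other cells moved with these: the plasma cell genes Jchain and Igkc were at 10.2 ± 10.3 and 42.8 ± 38.2 CPM in GvHD and 0.192 ± 0.501 and 4.72 ± 2.94 in BMT libraries, and the NK cell genes Ncr1 and Fcer1g at 3.69 ± 3.90 and 2.95 ± 1.61 against 0.421 ± 0.860 and 0.710 ± 0.951. Dendritic cell genes rose in 6 of 7 (6 adjusted over the list alone; camera adjusted p = 0.000658). The test called 3879 of 13185 genes, 1870 higher in GvHD. Calls numbered 2297 without experiment 3, 1905 per donor culture and 2135 with the PCR cycle number as a factor.

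In the colon, GvHD cells again held more Gzmb, at 4595 ± 1840.0 CPM in 12 libraries against 414 ± 128 in 12 (log2 fold change 3.44 ± 0.22, adjusted p = 9.12e-12). The chemokine gene Ccl4 rose by 3.35 ± 0.22 (adjusted p = 1.74e-11), Il10 by 2.07 ± 0.12 (adjusted p = 2.10e-12) and Ctla4 by 0.95 ± 0.07 (adjusted p = 1.28e-10). Ccr7 fell by 2.24 ± 0.14, Il1rl1 fell by 1.13 ± 0.09 and Rora fell by 0.82 ± 0.09, and the fibronectin gene Fn1, also a gene of stromal cells, was at 9.18 ± 7.11 against 67.7 ± 15.7 CPM. Each of these genes parted the 12 libraries of one model from the 12 of the other. Mki67, unlike in spleen and liver, fell by 0.67 ± 0.12 (adjusted p = 4.80e-05). Foxp3 rose by 0.20 ± 0.08 (adjusted p = 0.0353), but the rise was gone without libraries above 1000 CPM of epithelial markers (-0.01 ± 0.10, adjusted p = 0.943). Cytotoxic and effector molecules rose in 13 of 17 with 2 lower (13 and 2 adjusted over the list alone; median 1.01, camera adjusted p = 3.82e-09), whereas dendritic cell genes fell in 6 of 7 (6 adjusted over the list alone; camera adjusted p = 0.000550). Epithelial genes fell in 15 of 16 (16 adjusted over the list alone; camera adjusted p = 0.000104, adjusted p = 0.597 with an estimated correlation), their sum being 276 ± 276 CPM in GvHD and 1398 ± 791 in BMT recipients. Endothelium and stroma genes fell in 6 of 7 (7 adjusted over the list alone; camera adjusted p = 0.0128, adjusted p = 0.532 with an estimated correlation), with Col1a2 at 1.37 ± 1.48 against 23.6 ± 24.8 and Acta2 at 0.644 ± 0.399 against 5.82 ± 4.88 CPM. The test called 6257 of 13082 genes, 3124 higher in GvHD. It called 3445 without experiment 7, 2191 per donor culture, 3870 with the PCR cycle number as a factor, 3465 with the epithelial sum as a term and 1762 without libraries above 1000 CPM of epithelial markers.

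**Figure D3:**
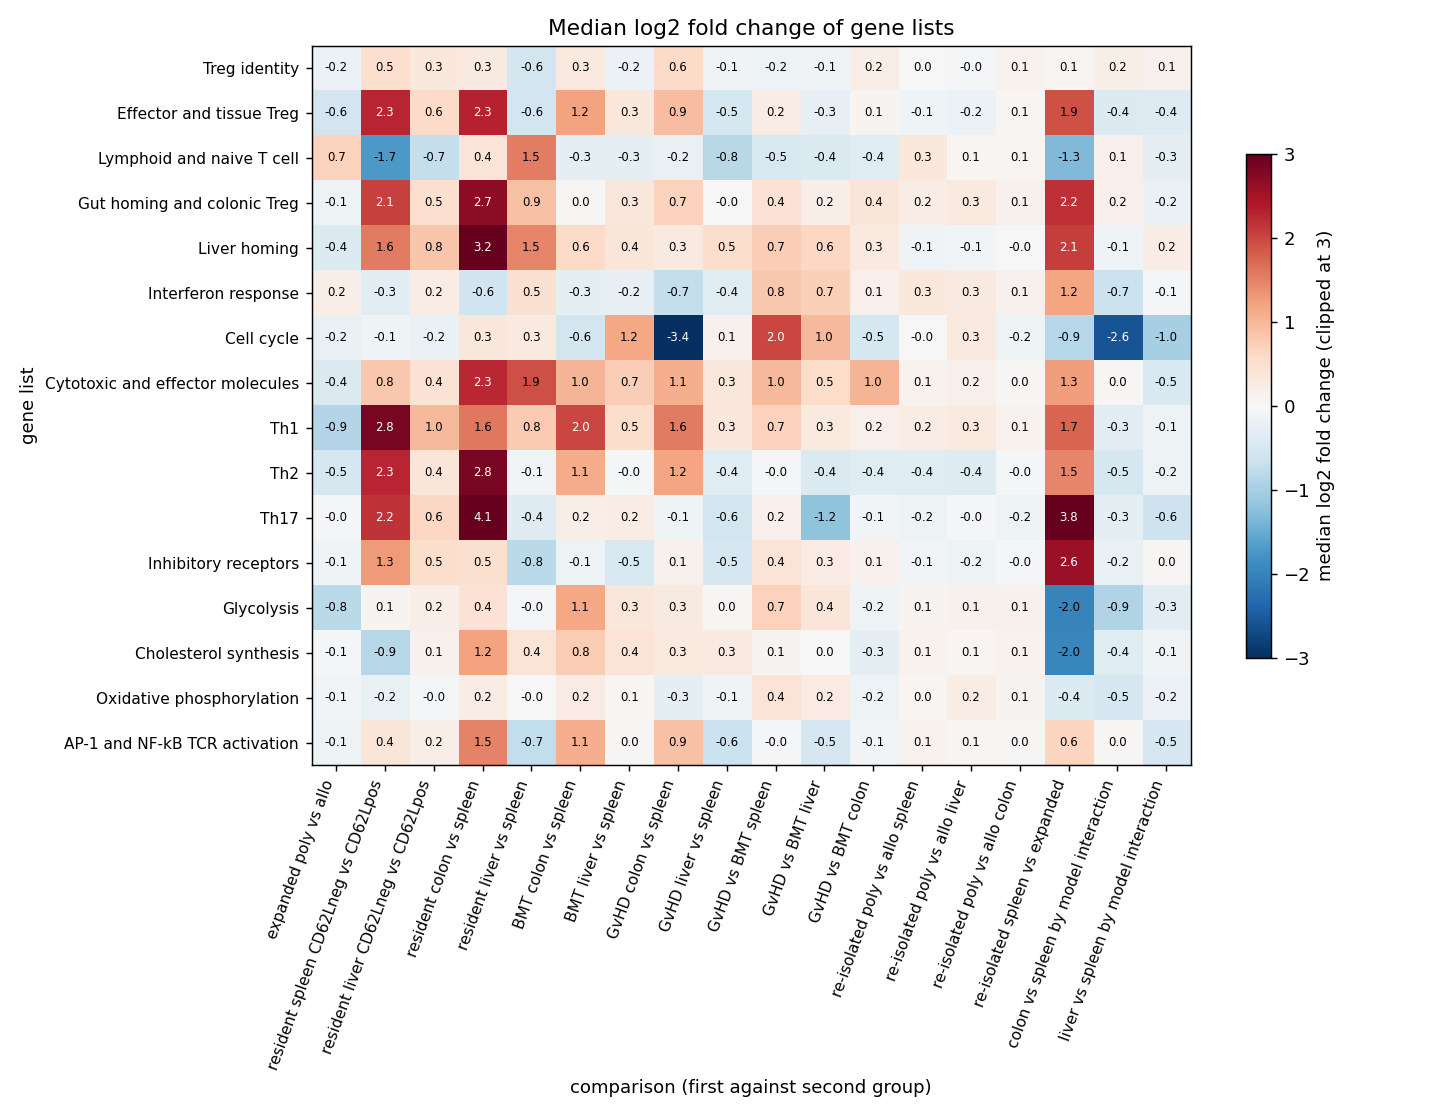
Median log2 fold change of 16 gene lists (down) in the comparisons between tissues, models and cultures (across), on a colour scale clipped at 3. The cell cycle list lies at 2.01 for GvHD against BMT spleen and -3.36 for GvHD colon against spleen.

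Genes called in both resident and re-isolated cells were counted, with transcripts of other cells and early response genes left in. In colon against spleen, 5004 genes were called in the same direction in resident cells and in BMT recipients, where 2307 would be shared by chance among 12905 genes, and 371 were called in opposite directions. In GvHD recipients 3563 were shared (1861 by chance) and 699 opposed. Across genes, which are not independent replicates, Pearson's r of the changes with those of resident cells was 0.717 in BMT and 0.413 in GvHD recipients. Rora was among the shared genes, with 4.09 ± 0.09 in resident cells, 3.83 ± 0.07 in BMT and 3.44 ± 0.12 in GvHD recipients, as was Il1rl1 with 5.61 ± 0.16, 2.77 ± 0.08 and 2.04 ± 0.14. In liver against spleen 1457 genes were shared with BMT recipients (585 by chance, 235 opposed, r 0.404) and 1164 with GvHD recipients (359 by chance, 157 opposed, r 0.367). The resident and re-isolated lists share no library. Liver libraries had more second PCR cycles than spleen libraries in resident cells, and on average in both models. Shared genes were not counted with the cycle number as a term, so its part in the liver overlap was not tested. Resident cells here were CD62L-negative, while the labels give no CD62L gate for re-isolated cells.

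Poly and allo cells were compared after transfer, with counts summed per culture (4 poly and 4 allo), to ask whether the stimulus leaves a trace. In the spleen Igfbp4, an insulin-like growth factor binding protein gene of naive T cells, was at 21.7 ± 7.62 CPM in poly and 3.22 ± 1.36 in allo cells, means and SD being over cultures (log2 fold change 2.71 ± 0.35, adjusted p = 0.0251). The adaptor gene Grap2 rose by 0.71 ± 0.09 (adjusted p = 0.0251). Both were without overlap, which 1 gene in 35 shows by chance with the experiments left aside, but the naming rule favours such genes. Penk did not pass (-1.69 ± 0.27, adjusted p = 0.0729; -1.65 ± 0.24, adjusted p = 0.0131 with the experiment as a replicate block). The lymphoid and naive list rose in 2 of 15 (8 adjusted over the list alone; 8 in the paired fit; median 0.32, camera adjusted p = 1.94e-17, adjusted p = 0.182 with an estimated correlation), and interferon genes in 0 of 28 (14 adjusted over the list alone; 7 paired; median 0.31, camera adjusted p = 2.88e-21, adjusted p = 0.182 with an estimated correlation). Spleen calls numbered 19 of 15923, 8 higher in poly cells, 267 in the paired fit, 237 by DESeq2, 22 by limma, 422 with no filter on low counts, and 0 to 1 when 1 experiment was left out. In the liver Penk fell by 1.99 ± 0.26 in poly cells (adjusted p = 0.0230), from 66.7 ± 19.2 to 17.9 ± 8.49 CPM, Lag3 fell by 0.99 ± 0.17 (adjusted p = 0.0478) and Grap2 rose by 0.80 ± 0.12 (adjusted p = 0.0313), each without overlap. Liver calls numbered 23 of 15882, 3 higher in poly cells, 113 in the paired fit, 188 by DESeq2, 10 by limma, 343 with no such filter, and 0 to 30 with 1 experiment left out. In the colon edgeR called 0 genes, with 299 of 16012 at an unadjusted p under 0.05, DESeq2 called 22 and limma 3. Penk averaged 126 against 255 CPM there (-1.10 ± 0.23, adjusted p = 1.00), with all 4 poly cultures below all 4 allo cultures. On simulated 2-fold changes the spleen, liver and colon tests recovered 82, 70 and 48 %. These lay in genes well above the count filter and without structure by experiment, so real recovery may be lower.

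**Figure D4:**
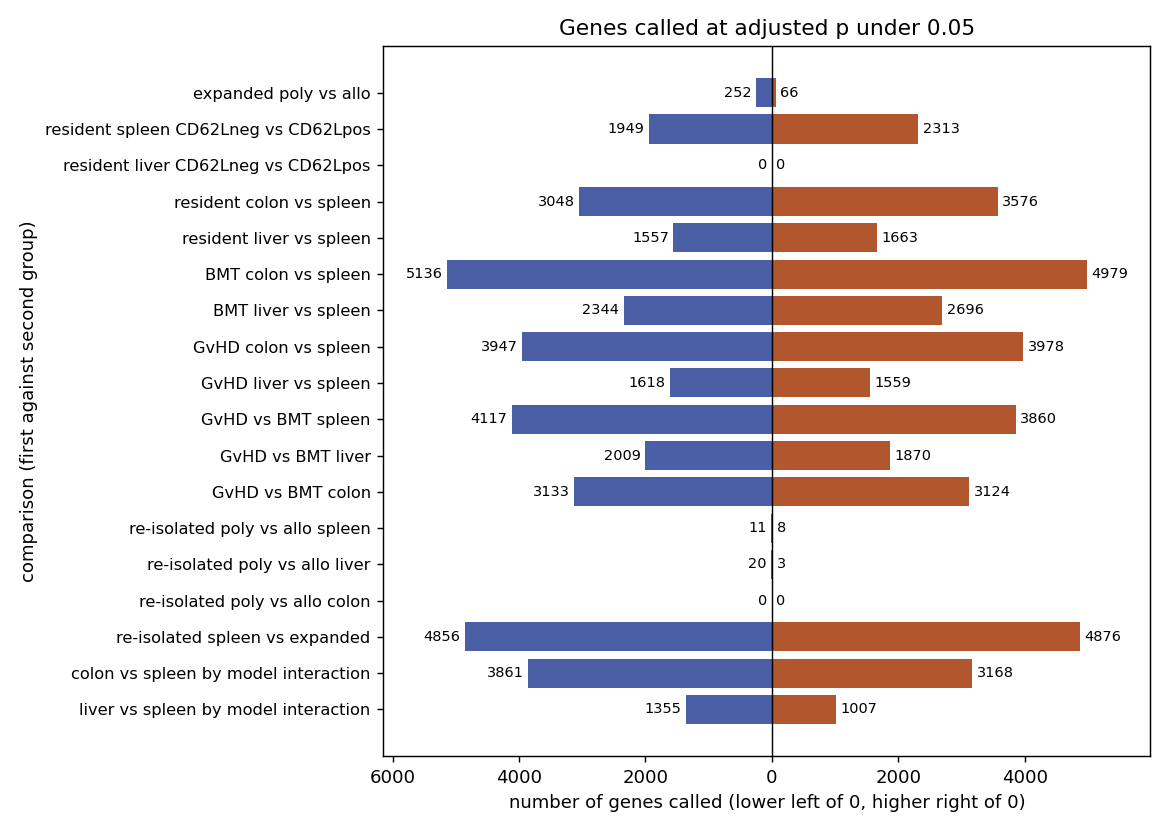
Genes called higher (right of 0) and lower (left of 0) at adjusted p under 0.05 in the 18 comparisons, as bars in numbers of genes. Counts run from 0 for poly against allo cells of the colon to 10115 for BMT colon against spleen.

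**Figure D5:**
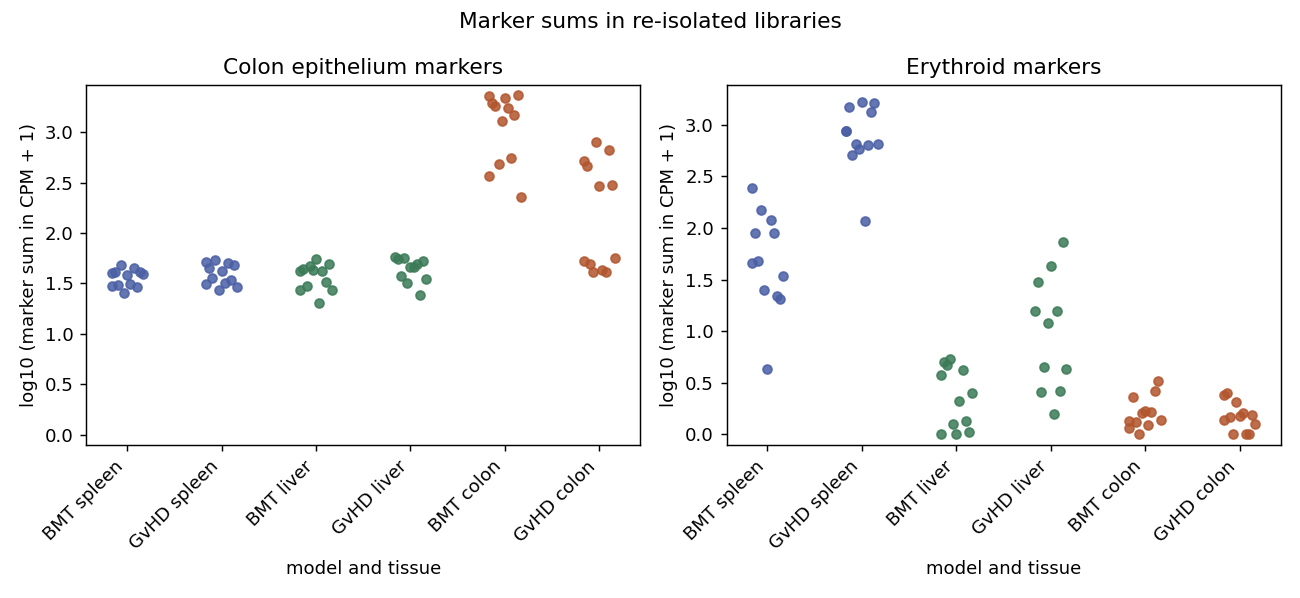
Sum of colon epithelial (left) and erythroid (right) marker CPM, as log10 (CPM + 1), in each re-isolated library by tissue and model. The sums averaged 1398 ± 791 CPM of epithelial markers in 12 BMT colon libraries and 920.3 ± 499.8 of erythroid markers in 12 GvHD spleen libraries.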

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

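The test of the PCR cycle number for differences between the models, the test of a wrong label on 1 liver library and the limits on epithelial and erythroid transcripts were chosen after results had been seen, and the other tests of this part before.

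Groups of 4 to 6 libraries were tested for a library far from the others in each of 5 quantities, and 10 of 95 such tests found one, where chance gives it in about 1 in 20 groups, or 4.75 times. In GvHD liver poly cells recipient 2-5 had 43519000 total counts, against 11894600 to 12259600 in the others, and a B and plasma cell marker sum of 498 CPM against 199 to 239. In GvHD colon poly cells recipient 2-5 had 8657810 total counts against 11289500 to 12078500, and recipient 3-5 a B and plasma cell sum of 160.5 CPM against 86.1 to 99.7. In GvHD colon allo cells recipient 3-2 held 521 CPM of Foxp3 against 396 to 423, and recipient 3-3 held sums of 159 CPM of B and plasma cell markers against 86.8 to 108 and of 1.51 CPM of erythroid markers against 0 to 0.542. The erythroid sum was 1.64 CPM in BMT colon poly cells of recipient 7-5, against 0.221 to 0.595, and 10.9 in GvHD liver poly cells of recipient 3-6, against 0.572 to 3.28. The resident spleen CD62L-positive library 2 had a B and plasma cell sum of 197 CPM against 148 to 153. The change from spleen to colon differed between GvHD and BMT recipients in 7029 genes and that from spleen to liver in 2362, each by a test of the difference itself.

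Epithelial transcripts were high in BMT colon libraries, with a marker sum of 1398 ± 791 CPM (SD, 12 libraries) and with Dmbt1 at 417 ± 272, Muc2 at 293 ± 223 and Krt8 at 216 ± 119, although the cells were sorted for Foxp3-GFP. The 16 markers rose and fell together over the 12 libraries, with a median pairwise Spearman rho of 0.829 (a description, as the pairs share libraries), which epithelial cells or their RNA in the libraries would give and a program of the T cells could give too. Expanded cultures hold 4 of the 16 markers at over 1 CPM, and no other list holds any. Among libraries with 13 second PCR cycles, 5 of GvHD and 8 of BMT colon had median sums of 521 and 1620.1 CPM, with an exact permutation p of 0.0932 over 1287 splits. The rule set beforehand would have read this p as pointing to the cycle number, but a p that misses the threshold does not show equal sums, so the cycle number stays open, as does an unequal share of epithelial cells between the models.

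The CD62L gates differed less in resident liver than in spleen. Over 1487 genes that differ at least 2-fold between the gates in spleen, 83.1 % had the same sign in liver, and the median liver change was 0.310 of the median spleen change, as CD62L-positive cells in the CD62L-negative liver libraries would give, and as weaker changes in liver cells themselves could. The genes were chosen by their change in spleen, which by itself lowers the ratio of liver to spleen change. CD62L-positive replicate 3 comes from the mouse without a CD62L-negative library. Without it 275 genes were called, and 626 with it counted as CD62L-negative. The ratio of the changes was 0.438 without it. This argues against a wrong label on it as the whole cause, though the choice of genes lowers this ratio too. The label of this library, the purity of the sort and a state of liver cells between the gates stay open.

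GvHD and BMT cells differed in 7977 genes in spleen, 3879 in liver and 6257 in colon, and the experiments of the models do not overlap, so disease cannot be told apart from the experiment: between the experiments of GvHD and of BMT the test called 3562 and 2639 genes in spleen, 161 and 1217 in liver, 3763 and 2141 in colon. The number of second PCR cycles as the whole cause is argued against, as 6916 genes were called in spleen with it as a covariate, 2594 in liver and 4308 in colon, and 6913, 2135 and 3870 with it as a factor, which leaves a part open in liver and colon. Erythroid RNA in GvHD spleen libraries (920.3 ± 499.8 CPM against 73.2 ± 69.4, with Slc4a1 at 191 ± 111 and Hbb-bs at 268 ± 142, in cells sorted for Foxp3-GFP) as the whole cause of the cell cycle rise is argued against as well, since 28 of 28 cell cycle genes were called higher with the erythroid sum as a term, with the median at 1.28 from 2.01. Interferon genes numbered 24 of 28 then, with the median at 0.65 from 0.82, and 2 of 11 erythroid markers exceed 1 CPM in expanded cultures. The disease, the experiment and a part of the difference from erythroid cells stay open.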

How the results depend on the processing

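Among the alternatives, the PCR cycle number as a factor, the limits on epithelial and erythroid transcripts and those transcripts as terms were chosen after the data had been seen, and the median erythroid limit after the counts of the 500 CPM limit. Over 23 results and 149 values under other settings, 105 lay within 1.5 times the reported count and 44 did not, and of 86 values with a library or experiment left out 67 did. Of 2015 values of the named genes 1 reversed, 62 lost and 22 gained the threshold. The reversed value is Foxp3 in GvHD against BMT colon, 0.20 ± 0.08 with all libraries and -0.0148 ± 0.0975, adjusted p = 0.943 under the epithelial limit, and it did not pass with the PCR cycle number as a factor either (0.11 ± 0.08, adjusted p = 0.330). No scaling moved the median of all genes by over 0.1 on the log2 scale. Except where fewer samples or genes tested give it, the cause was not tested.

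DESeq2 called 657 genes in expanded cultures (209 higher in poly, 31.8 % against 20.8 %), and after transfer 237 in spleen, 188 in liver (57 higher in poly, 30.3 % against 13.0 %) and 22 in colon. RLE factors gave 15 in liver poly against allo cells. On the normalized table limma called 10 there (3 higher in poly cells) and 3 in colon, and in the colon interaction 2407 higher and 4471 lower, so 35.0 % higher against 45.1 %. With no filter on low counts the calls were 192 for the resident liver gates and 422, 343 and 88 for poly against allo cells of spleen, liver and colon.

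Paired with a replicate block, expanded cultures gave 596, the resident liver gates 531, resident liver against spleen 2079, and poly against allo cells of spleen, liver and colon 267, 113 and 3. In the resident liver gates the block also takes CD62L-positive replicate 3, whose mouse has no pair, out of the contrast, and the unpaired test without that library called 275. Apart from the values given beside single results, the block changed no other call and moved no other count by over 1.5 times. Counts summed per culture gave 5003, 1905 and 2191 for GvHD against BMT spleen, liver and colon, with fewer samples. Recipients as replicates gave for poly against allo cells 165 in BMT and 677 in GvHD spleen, 136 in GvHD liver, 46 in BMT and 3 in GvHD colon.

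The PCR cycle number as a covariate gave 3102 for BMT liver against spleen, and as a factor 2705 there, 1932 for GvHD liver against spleen, 2135 for GvHD against BMT liver and 3870 for colon. The epithelial limit of 1000 CPM, which 8 of 12 BMT colon libraries exceed, gave 1762 for GvHD against BMT colon and 3844 for the colon interaction, and the epithelial sum as a term 3465. Without the 6 GvHD spleen libraries above the median of erythroid markers (763 CPM) GvHD liver against spleen gave 1877 and the liver interaction 1113. The 500 CPM limit leaves 1 of 12 such libraries, assumed to vary like the others, and gave 852 for GvHD colon and 218 for GvHD liver against spleen, 1394 for GvHD against BMT spleen, 1177 and 127 for the colon and liver interactions. The erythroid sum as a term gave 2905 for GvHD against BMT spleen. At an adjusted p under 0.01 the shared liver genes were 873 with BMT and 672 with GvHD recipients. Of 217 gene list calls 66 passed with an estimated correlation.

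With 1 library or experiment left out, the counts ran from 132 to 288 in expanded cultures (132, 157, 133 and 175 without experiment 4, 5, 6 and 7), 0 to 275 for the resident liver gates (highest without CD62L-positive replicate 3), 2004 to 2566 for GvHD liver against spleen (lowest without experiment 3), 5278 to 8697 and 2297 to 3825 for GvHD against BMT spleen and liver (lowest without experiment 3), 3445 to 7881 for colon and 4068 to 7466 for the colon interaction (lowest without experiment 7), 1241 to 2480 for the liver interaction (1302, 1241 and 1491 without experiment 2, 3 and 7), and for poly against allo cells 0 to 1 in spleen (whichever of the 4 experiments is left out) and 0 to 30 in liver (0 without experiment 2 or 3). In the other comparisons no library or experiment left out moved the count by over 1.5 times. For the shared genes and the gene lists nothing was left out. At the depth of 7792440 counts per library and more, genes with few counts limit the tests: the filter kept 12698 of 53465 genes in expanded cultures.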

Other observations

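The splits of expanded and resident cells, of tissues against spleen and of GvHD against BMT spleen and liver were described as tests only after their counts had been seen, and the other splits before.

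Genes of regulatory T cell identity moved with tissue. In resident liver against spleen 12 of 16 fell and 1 rose (none rose with the mouse as a block; 1 and 12 adjusted over the list alone; median -0.56, camera adjusted p = 4.26e-07, adjusted p = 0.0794 with an estimated correlation), with Izumo1r at -1.70 ± 0.10, adjusted p = 4.78e-08. In GvHD colon against spleen 9 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.57, camera adjusted p = 0.00132, adjusted p = 0.0398 with an estimated correlation and 0.157 with it when paired), and in BMT liver 8 fell and 2 rose (2 and 8 adjusted over the list alone; median -0.18, camera adjusted p = 0.000116). In resident colon 9 rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.783), where the median (0.27) and mean (0.01) lie above 0 and the test points down. B and plasma cell genes rose in 6 and fell in 3 of 12 in resident colon (6 and 4 adjusted over the list alone; camera adjusted p = 0.829), and fell in 4 of 5 in GvHD colon (4 adjusted over the list alone; camera adjusted p = 0.000657). CD8 T and NK cell genes rose in 4 of 5 from expanded cells to spleen (4 adjusted over the list alone; camera adjusted p = 0.0307, adjusted p = 0.0883 with an estimated correlation). Hepatocyte genes passed the filter in poly against allo cells alone, 6 in liver and 3 in colon, with 0 called in each by edgeR (list adjusted p = 0.459 and 0.421), and their sum was 8.13 ± 7.68 CPM in BMT liver libraries.

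The samples of each comparison were also split in other ways into groups of the same sizes, and chance can be excluded where under 1 in 20 splits, the real one included, call as many genes. It can be excluded for expanded cultures (1 of 61 splits, real 318, highest other 0, and 1 of 32 splits that part all pairs, highest other 0) and resident colon against spleen (1 of 100 splits, real 6624, highest other 2367, with 8 of 9 samples on the real side). The same holds for BMT colon (1 of 61 splits, real 10115, highest other 126) and liver (1 of 61 splits, real 5040, highest other 0) and GvHD colon (1 of 61 splits, real 7925, highest other 0) and liver against spleen (1 of 61 splits, real 3177, highest other 0). Of 40 splits that part as many pairs 1 called as many in each of these 4, and the highest others were 9376 in BMT colon and 3555 in BMT liver, each with 22 of 24 samples on the real side, 946 in GvHD colon (14 of 24) and 1794 in GvHD liver (21 of 23). Spleen against expanded cells gave 1 of 100 splits, real 9732, highest other 1, with single libraries as units. Several recipients share a donor culture, which these splits leave aside, so they do not exclude chance for cultures.

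In the other comparisons the design allows too few splits for such a share. The recipients of both models come from 4 experiments, which part into 2 and 2 in only 3 ways. Splits of single libraries or recipients, which leave this aside, gave for GvHD against BMT spleen 1 of 98 splits, real 7977, highest other 4151 (18 of 24 samples on the real side), liver 1 of 98 splits, real 3879, highest other 0 and colon 1 of 98 splits, real 6257, highest other 0, and for the colon interaction 1 of 100 splits, real 7029, highest other 3 and the liver interaction 1 of 100 splits, real 2362, highest other 24. Splits by experiment across the models called 62 and 656 genes in spleen, 344 and 29 in liver, 1432 and 153 in colon. They were fitted without a model term, so the difference between the models widens the spread on both sides. These counts therefore cannot show that experiments differ little. Within 1 model the 2 experiments differed in 3562 (GvHD) and 2639 (BMT) genes in spleen. The resident spleen gates, resident liver against spleen and poly against allo cells after transfer are paired, with 8 splits that part as many pairs. Among these the real 4262 genes of the spleen gates, 3220 of resident liver, 19 of poly against allo spleen and 23 of liver stand beside a highest other of 0 in each. With the pairs left aside the spleen gates gave 1 of 35 splits, real 4262, highest other 1, resident liver 1 of 35 splits, real 3220, highest other 0, poly against allo liver 1 of 34 splits, real 23, highest other 0 and spleen 2 of 34 splits, real 19, highest other 470. The split with 470 genes parts experiments 2 and 7 from 3 and 6, and as several times the real count it points to a structure of the samples by experiment, while 267 genes were called with the experiment as a replicate block. The split by model could not be fitted beside the model term in the poly against allo comparisons.

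For the resident liver gates and poly against allo cells of the colon the real count was 0 by edgeR, so any split calls as many (61 of 61 and 34 of 34) and the splits say nothing of chance. At an unadjusted p under 0.05 lay 939 and 299 genes, DESeq2 called 0 and 22, and limma 0 and 3. In liver the highest other was 0, but of the 16 splits that part all 4 pairs 1 called 626 genes. It differs from the real one by CD62L-positive replicate 3 alone, whose mouse has no pair, and points to a structure of the samples. Splits of the paired fit, which called 531 genes, were not run. In colon the highest other, 50, parts experiments 2 and 6 from 3 and 7, with 3 genes when the experiment is a block.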
